A study of Mus musculus with 15 samples.

How the data were processed

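The series comes from a mouse model of the kinase mTOR and holds 15 samples of sorted haematopoietic stem cells (HSC) from mice given poly(I:C), the inducer of the Mx1-Cre recombinase. Of these, 12 are RNA-seq samples, 4 per genotype, which were not analysed here because no processed values for them were used here. The other 3 are ATAC-seq libraries, 1 per genotype, in which a transposase cuts accessible DNA. Per the labels' protocols, 50000 sorted cells entered each transposition, which ran for 30 min at 37 °C. The genotypes were WT control (floxed Mtor without Cre), KO (floxed Mtor with Cre) and KI (Cre with a floxed and a knock-in Mtor allele), and each library took its group from its label. The labels mark the WT and KO libraries as re-analysed and the KI library not, so that any batch difference and the KI genotype cannot be told apart. Both mutants carried Cre and WT did not. In comparisons with WT, an effect of Cre itself therefore cannot be told apart from one of the Mtor alleles.

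Each deposited file was a peak list of 5 columns without a header, with 1 file per library, so peaks were called per library and not on pooled samples. The peak names in the files are those written by MACS. The fifth column is the score the authors deposited for each peak, read here as the form MACS writes, 10 times the negative log10 of the peak's p-value, with a lowest value of 50. Per the submitters' processing notes the build was mm10 and CASAVA was used. The aligner, the MACS version, the handling of duplicate reads, any shift of reads for the transposase, any control and the filters are not given in the sources used here. Read depth is unknown. A deeper or cleaner library yields more weak peaks at the same score threshold, so list length is no measure of accessibility. The score was used to describe, rank and filter peaks within their own list and was never compared between lists.

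Peaks on chromosomes 1 to 19, X and Y were kept. A peak counted as shared when at least 1 bp overlapped a peak of the other list (bedtools 2.31.1), and otherwise as absent from that list. Shares carry Wilson 95% intervals, which cover counting error over peaks and nothing else. With 1 library per genotype there is no replicate check, no test between genotypes and no p-value, and peaks are not replicates. The Jaccard index is the length covered by both lists over the length covered by either. The 3 lists were merged where peaks overlapped or touched, and each merged region was classed by the lists with a peak in it. The number of WT peaks absent from both mutants was set beside that of independent lists (n1 × n2 / N), over all peaks and within 10 classes of WT score. Simulating unchanged libraries against the WT library was not possible from peak lists, and part of any excess may come from the shared WT list. Strong peaks were the top 25% of a list by score.

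Genes came from a RefSeq table of GRCm38.p6, the assembly behind mm10, which gives the start and end of each gene but no strand. The planned promoter peak was therefore replaced by a gene-end peak, a peak within 1 kb (1000 bp) of either annotated end of a gene. Such a peak can lie at the 3' end or belong to a neighbouring gene. The gene set held 21890 genes, 21887 of them protein-coding and 3 list genes of another class (Mx1, Mx2 and Tpsab1). As a check of the build, 50.7% of WT, 46.3% of KO and 38% of KI peaks lay at gene ends, against 5.44%, 5.23% and 5.39% after moving the peaks by 1 Mb.

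The 24 gene lists, 9 of cell type markers and 15 of pathways, held 616 genes and were fixed before the data were examined, as were the comparisons, most alternatives and the rule for named genes. All 616 genes were matched, 1 of them by an older name, and 22 were in more than 1 list. A gene was called lost when it had a gene-end peak in WT and none in the mutant, and gained in the opposite case. Overlap of the peaks themselves was not checked for these calls. A gain or loss can therefore arise where peaks of both lists overlap and only 1 reaches the 1 kb window. The number lost was given as a percentile among 10000 random lists of genes with a WT gene-end peak, matched on 5 classes of their WT score. The number gained was set among 10000 random lists of genes without such a peak. After the data were examined, draws from the list genes without a WT gene-end peak, and draws matched on nearby WT peaks and gene length, were added. Peaks in the gene body or within 10 kb of it were counted per list, and their list-specific peaks, each counted once per gene it lay near, were set among 2000 matched random lists, also an addition. Differences of such shares carry Newcombe 95% intervals, added after the data were examined.

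Genes were named by this rule: Mtor; for each pair and direction, the 10 highest-scoring strong peaks at a gene end that the other list lacked and the 5 highest-scoring farther ones, by the nearest gene within 50 kb; and for each gene list up to 4 members that differed from WT in KO or KI, in order of score. Genes named outside it are said to be so, and some genes the rule selects are not reported here.

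The steps were tested on simulated data made from the WT list against an altered copy. Of 2000 removed peaks 1993 were found and 0 kept peaks were called absent, and 3000 of 3000 added peaks were found. Among 9678 genes, a list of 30 genes with 15 planted losses reached percentile 100, and 200 lists without excess averaged percentile 51.2. The simulated losses were drawn without regard to score, so absence that depends on score was not tested. Alternatives were a reciprocal overlap of 50%, a tolerance of 1 kb, the 17316 strongest peaks of each list (equal list size), the stronger 50% of each list, peaks set to 200 bp, autosomes only, merging across 500 bp, strong peaks as the top 10% or 50%, gene ends within 500 or 2500 bp, and random lists without matching. Motif content was left out because no genome sequence was used here. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.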

Results

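Accessible chromatin was profiled by ATAC-seq in sorted HSC of WT, KO and KI mice, with 1 library per genotype. The WT list held 17316 peaks covering 11.6 Mb, the KO list 19189 peaks covering 11.5 Mb and the KI list 28391 peaks covering 16.5 Mb. The KI list was thus 1.64 times as long as the WT list, at an unknown read depth. There were no replicates, so each difference below is between libraries and carries no replicate error. The series title gives the purpose as the kinase-independent role of mTOR, for which loss of the protein (KO) and a changed allele (KI) are set against WT and against each other.

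The targeted gene was examined first. Mtor, which encodes the kinase at the core of the mTORC1 and mTORC2 complexes, spans chromosome 4 from 148448582 to 148557685 (mm10). A peak lay over its annotated start in WT (148448060 to 148449268, score 341.21) and in KI (148448229 to 148448836, score 210.27), and the KO list had none there. In WT this peak ranked 570 of 17316. Weaker peaks about 3.6 kb upstream of the start (3558 bp in WT, 3676 bp in KO and 3617 bp in KI) and inside the gene near 148509457 were present in all 3 lists. KI had a further peak 557 bp past the annotated end. The presence or absence at the start was the same with gene ends taken within 500 or 2500 bp and at equal list size.

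**Figure D1:**
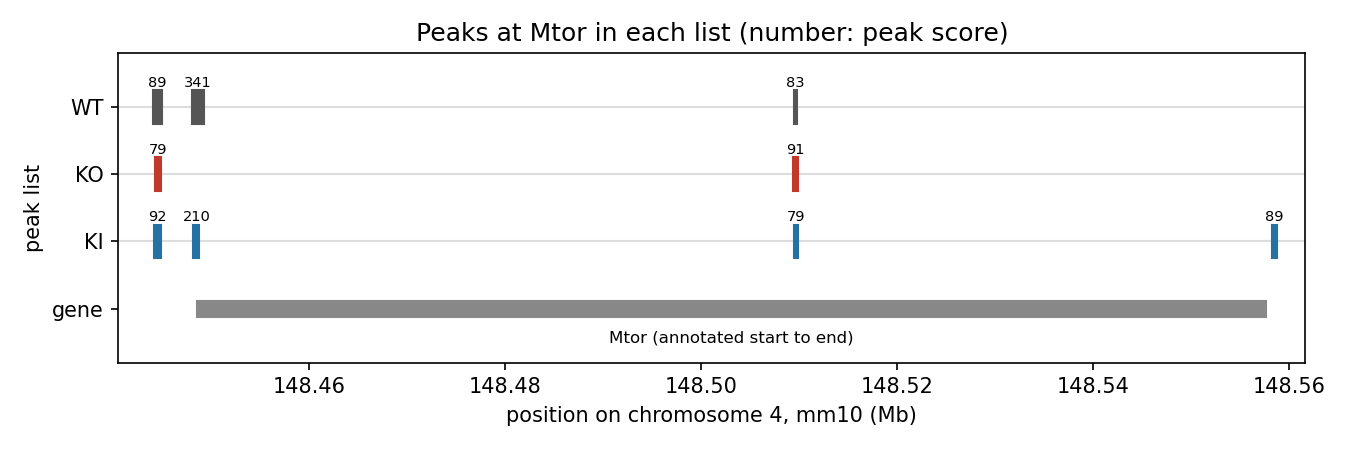
Peaks at Mtor on chromosome 4 (x axis, mm10 position in Mb) in the WT, KO and KI lists (y axis), drawn to scale above the annotated gene, with each peak's score. The peak over the annotated start is present in WT (341.21) and KI (210.27) and missing from KO, while the upstream and internal peaks are in all 3 lists.

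Gene-end peaks made up 50.7% of the WT list (95% interval 49.9 to 51.4), 46.3% of KO (45.6 to 47.0) and 38% of KI (37.4 to 38.6). Intergenic peaks made up 22.8% of WT, 25.2% of KO and 29.2% of KI, and the remainder lay in gene bodies. Median peak width was 590 bp in WT, 514 bp in KO and 477 bp in KI. The gene-end shares at equal list size were 50.7% in WT, 48.4% in KO and 50.6% in KI. Chromosome Y held 13 WT, 15 KO and 18 KI peaks.

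The first comparison, WT against KO, asks what differs when Mtor is deleted. Beside the Mtor start itself, KO lacked WT peaks at the ends of Bop1, a ribosome biogenesis factor, Sptb, the erythroid beta-spectrin, Optn, an autophagy receptor, and Gba2, a glucosylceramidase. The Bop1 peak also overlapped Hsf1 and the Gba2 peak Rgp1, so neither can be assigned to 1 gene. KO had peaks that WT lacked at Trim12a, Slc12a3 and the receptor gene Ror1. Of the WT peaks, 4421 of 17316 (25.5%, 24.9 to 26.2) were absent from KO, and 6225 of 19189 KO peaks (32.4%, 31.8 to 33.1) were absent from WT. The lists had a Jaccard index of 0.499.

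Absence was concentrated among weak peaks. In the lowest 25% of WT scores 57.4% of peaks were absent from KO, and among strong peaks, the top 25%, 17 of 4329 (0.393%, 0.245 to 0.628). The highest-scoring of those 17 was the Mtor start. At gene ends it was followed by Zfp429 (187.29), Gba2 (181.74), Fam161a (169.32), Optn (164.72), Sptb (161.94), Eya1 (155.35) and Bop1 (155.23). Away from gene ends, peaks lay nearest to Nxf7 (4663 bp away, 219.55), Adora3 (8767 bp, inside Tmigd3, 195.46), Spag9, Chp2 and Cpne2. In the other direction, 48 of 4797 strong KO peaks (1.0%, 0.756 to 1.32) were absent from WT. They included gene ends of Zfp58 (189.33), Slc12a3 (176.33), Trim12a (175.48), Ror1 (168.3), Slc30a10 (165.81), Map7d1 (160.11), Lysmd2 (156.16), Eid2b (155.83) and Slc36a4 (152.13). Those farther away lay nearest to Mid1 on X (262.37), Gm51877 on chromosome 11 inside Sfi1 (228.73), Dock4, Stk25 and Pyroxd2. Sfi1 and the Mid1 region are present in repeated or variable copies in mouse genomes, where short reads do not always map uniquely. All 48 had a peak in KI. Gene-end peaks were 25.1% (23.9 to 26.4) of the WT peaks absent from KO and 59.4% (58.6 to 60.3) of those shared.

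**Figure D2:**
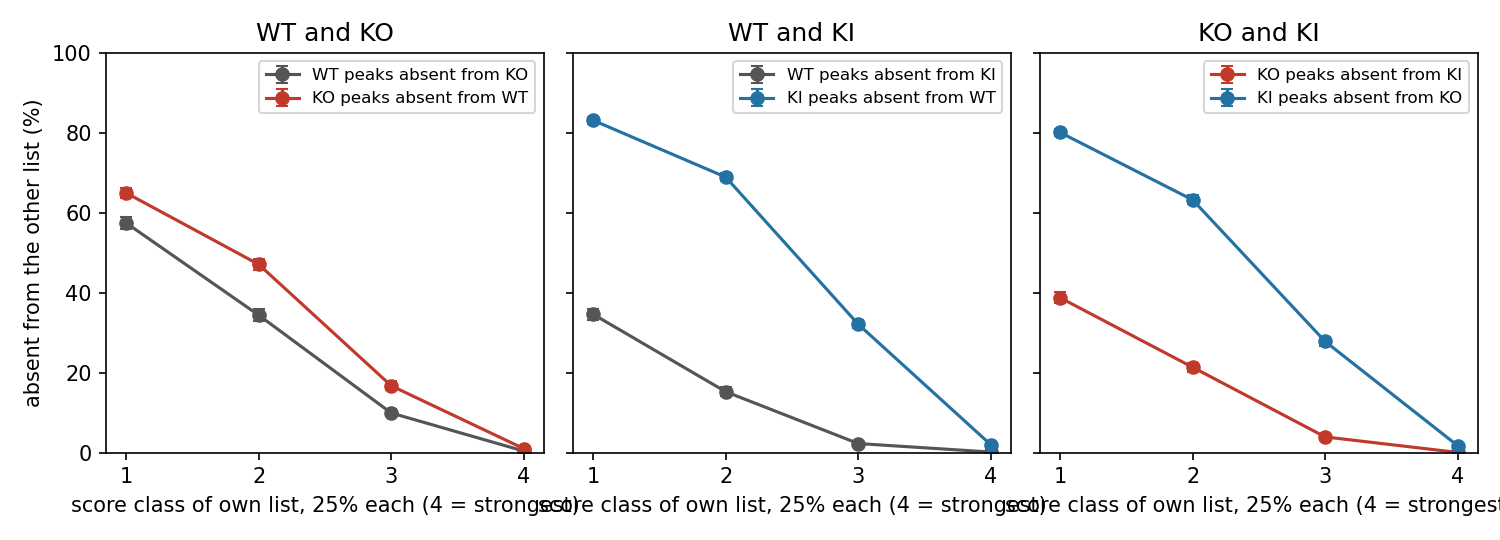
Share of peaks absent from the other list (y axis, %) by class of the score within their own list (x axis, 4 classes of 25% each, class 4 the strongest), for each pair of lists and both directions, with Wilson 95% intervals. In every pair the share falls from the weakest to the strongest class, for KI peaks absent from WT from 83.1% to 2.0%.

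The second comparison, WT against KI, asks what differs with the knock-in allele. KI kept the Mtor start peak and nearly all strong WT peaks. KI peaks that WT lacked included gene ends of Trim12a and Trim5, neighbouring genes of a restriction factor family, Txndc5, a protein disulfide isomerase, and Srxn1, a sulfiredoxin. Of the WT peaks, 2261 (13.1%, 12.6 to 13.6) were absent from KI, while 13216 of 28391 KI peaks (46.6%, 46.0 to 47.1) were absent from WT. The Jaccard index was 0.482. With lists of equal size, 4255 WT peaks (24.6%) were absent from KI and 4373 KI peaks (25.3%) from WT, where equal lengths force the directions to balance.

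Of the strong WT peaks, 6 of 4329 (0.139%, 0.0635 to 0.302) were absent from KI. They lay inside Aida (412.31, nearest gene end Brox), inside E030030I06Rik (267.05), at Zfp429 (187.29), near Spag9 (163.59), inside the imprinted gene Grb10 (160.87) and near Gm4981 (157.19). The Zfp429, Spag9 and Gm4981 peaks were absent from KO as well. Of the strong KI peaks, 142 of 7097 (2.0%, 1.70 to 2.35) were absent from WT and 117 of these had a KO peak. High-scoring ones at gene ends were Trim12a (320.93), Slc12a3 (293.68), Txndc5 (270.19), Trim5 (261.58), Srxn1 (236.8), Tssk6 (225.55), Kbtbd6 (225.36), Donson (217.46) and Mettl2 (215.61). Those farther away lay nearest to Gm51877 (346.16, inside Sfi1), Gm40363 (300.28), Ms4a20 (261.15) and Mid1 (241.96). All of these named peaks were also present in KO.

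The third comparison, KO against KI, sets loss of the protein against the knock-in allele. KI had peaks that KO lacked at the ends of Cish, a cytokine-induced inhibitor of STAT5 signalling, Bop1, the ribosomal protein gene Rpl32, Hif1an, which hydroxylates HIF1A, Med1, a Mediator subunit, Rhot1, a mitochondrial transport GTPase, and Mtor. Of the KO peaks, 3072 (16.0%, 15.5 to 16.5) were absent from KI, and 12270 KI peaks (43.2%, 42.6 to 43.8) were absent from KO. The Jaccard index was 0.474. With equal sizes the numbers were 4279 (24.7%) and 4408 (25.5%).

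Among strong KI peaks, 123 of 7097 (1.73%, 1.45 to 2.06) were absent from KO, and 98 of these had a WT peak. The highest-scoring at gene ends were Cish (314.78), Emilin1 (261.51), Bop1 (242.54), Tmco6 (227.81), Rpl32 (225.73), Hif1an (220.95), Med1 (214.68), Rhot1 (214.65), Mtor (210.27) and Mrpl58 (208.53). The Emilin1 peak also overlapped Khk and the Bop1 peak Hsf1. Others lay nearest to Rab6a (281.84, inside Mrpl48), Disc1 (251.31), Dgkz (240.74), Angpt1 (222.69), which encodes a ligand of the Tek receptor, and Dynll2 (220.28). In the opposite direction 2 of 4797 strong KO peaks were absent from KI, 1 of them 17098 bp from Lamp2 on X (144.02).

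Merging the lists gave 32764 regions, 12282 of them (37.5%) with a peak in all 3. Regions with KO and KI peaks and no WT peak numbered 3502, those with WT and KI peaks and no KO peak 2526, and those with WT and KO peaks and no KI peak 430. WT peaks absent from both mutants numbered 1808, against 577 for independent lists and 1121 for independent lists within classes of WT score. Part of the excess may come from the WT list that both comparisons share. Of the WT peaks absent from KO, 59.1% (57.6 to 60.5) were present in KI, against 12442 of the 12895 WT peaks shared with KO. Of the KO peaks absent from WT, 57.9% (56.7 to 59.1) were present in KI, against 96.5% (96.2 to 96.8) of those shared with WT. At equal list size the classes changed to 1745 regions with KO and KI alone, 1761 with WT and KI alone and 1094 with WT and KO alone. At that size 3126 regions had a WT peak alone and 3147 a KO peak alone.

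**Figure D3:**
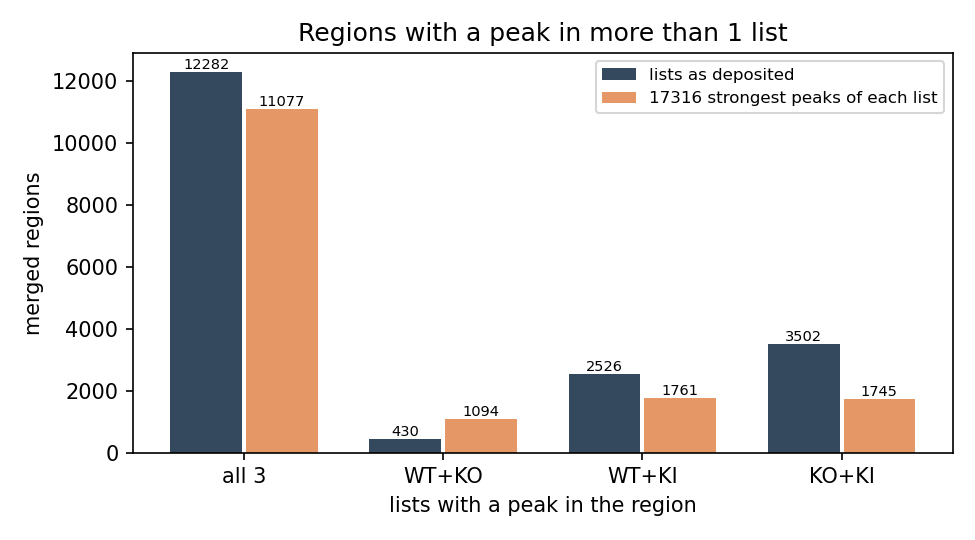
Merged regions (y axis, number) with a peak in all 3 lists or in exactly 2 of them (x axis), for the lists as deposited and for the 17316 strongest peaks of each. Regions shared by KO and KI alone exceed those shared by WT and KI alone in the full lists (3502 and 2526); at equal size the numbers are 1745 and 1761.

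Across all genes, 9678 had a gene-end peak in WT. In KO 1018 of these were lost and 1004 others gained, and in KI 319 were lost and 1897 gained. Of the 616 list genes, 366 had a gene-end peak in WT. KO lost 46 and gained 39, and KI lost 10 and gained 78, with 9 lost in both and 34 gained in both. At equal list size KO lost 49 and gained 33, and KI lost 33 and gained 40. Some genes named below scored near the lowest value of 50, such as H2-Aa (51.57 in KO), Slc16a3 (52.86 in WT) and Thy1 (58.28 in KI). Others scored higher, such as Bcl2l11 (150.4 in WT). In the lowest 25% of scores, 57.4% of WT peaks were absent from KO and 34.6% from KI. There 65.0% of KO and 83.1% of KI peaks were absent from WT. A single gene lost or gained may thus reflect the calling threshold.

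Among cell type markers, the erythroid list (24 genes, 6 with a WT gene-end peak) gained 5 members in KO and 9 in KI. Epor, the erythropoietin receptor, and Car1, a red cell carbonic anhydrase, were gained in both, and Sptb was lost in KO. These counts stood at percentile 99.2 in KO and 99.9 in KI of random genes without a WT peak, and at 91.8 and 95.4 of draws from the list genes. Among genes matched on nearby WT peaks and gene length they stood at 99.0 in KO and 99.97 in KI. The counts at equal list size were 3 and 5. The granulocyte and monocyte list (30 genes, 6 in WT) gained 0 in KO and 8 in KI, among them the myeloperoxidase gene Mpo, Csf1r, the macrophage colony-stimulating factor receptor, Irf8, a monocyte transcription factor, and Mmp8, a neutrophil collagenase. These gains stood at percentile 6.7 in KO and 98.5 in KI of random genes, and at 0.775 and 60.3 of draws from the list genes. It lost 3 in KO and 1 in KI. Its KI gain at equal list size was 1. Over the 24 lists in both mutants, 13 of 48 gain percentiles among random genes lay outside the middle 95%, all above it, and 5 of 48 among draws from the list genes: ribosomal protein and translation genes above in both mutants, B lymphoid genes below in both (1.85 and 0.365) and granulocyte and monocyte genes below in KO. Among genes matched on nearby WT peaks and gene length 10 of 48 did, all above: the haematopoietic stem cell gains (96.7 in KO and 97.3 in KI, from 97.7 and 98.5 without that matching) and the lysosome and autophagy gains in KI (96.3, from 98.3) fell inside the middle 95%. Chromatin regulators (96.1) and cell cycle genes (95.9) in KI and apoptosis genes in KO (91.8) stood at least as high among draws from the list genes as the erythroid list in the same mutant. Gains in both mutants are counted against the same WT list, so their percentiles are not independent. Of the 39 list genes gained in KO, 34 were also gained in KI.

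The haematopoietic stem cell list (30 genes, 14 in WT) lost 4 in KO and 1 in KI and gained 4 and 6. Procr, the endothelial protein C receptor used to mark HSC, was lost in both, Runx1, a transcription factor of definitive haematopoiesis, was lost in KO and kept in KI, and Cdkn1c, a cell cycle inhibitor, and Prdm16 were gained in both. The megakaryocyte and platelet list lost 3 in KO and 1 in KI and gained 2 in each. Gp5 was lost in both, Itga2b was gained in both and Gp1ba in KI.

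The other marker lists lost and gained members as well. The B lymphoid list lost Ebf1 in KO and gained Cd79a in KI. The T and NK lymphoid list lost 1 in KO and 0 in KI and gained 3 and 6, among them Eomes and Bcl11b in both and Thy1 in KI. The mast cell, basophil and eosinophil list lost Prg2 in both and gained Cpa3 and Il5ra in KI. The dendritic cell and antigen presentation list lost 2 in KO and 1 in KI, with Cd86 lost in both, and gained 2 in each, with H2-Aa in both, H2-Ab1 in KI and Clec9a in KO. The endothelial, stromal and mesenchymal list lost none and gained 3 in each, with Sox17 and Col1a1 in both, Col1a2 in KO and Pdgfrb in KI.

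**Figure D4:**
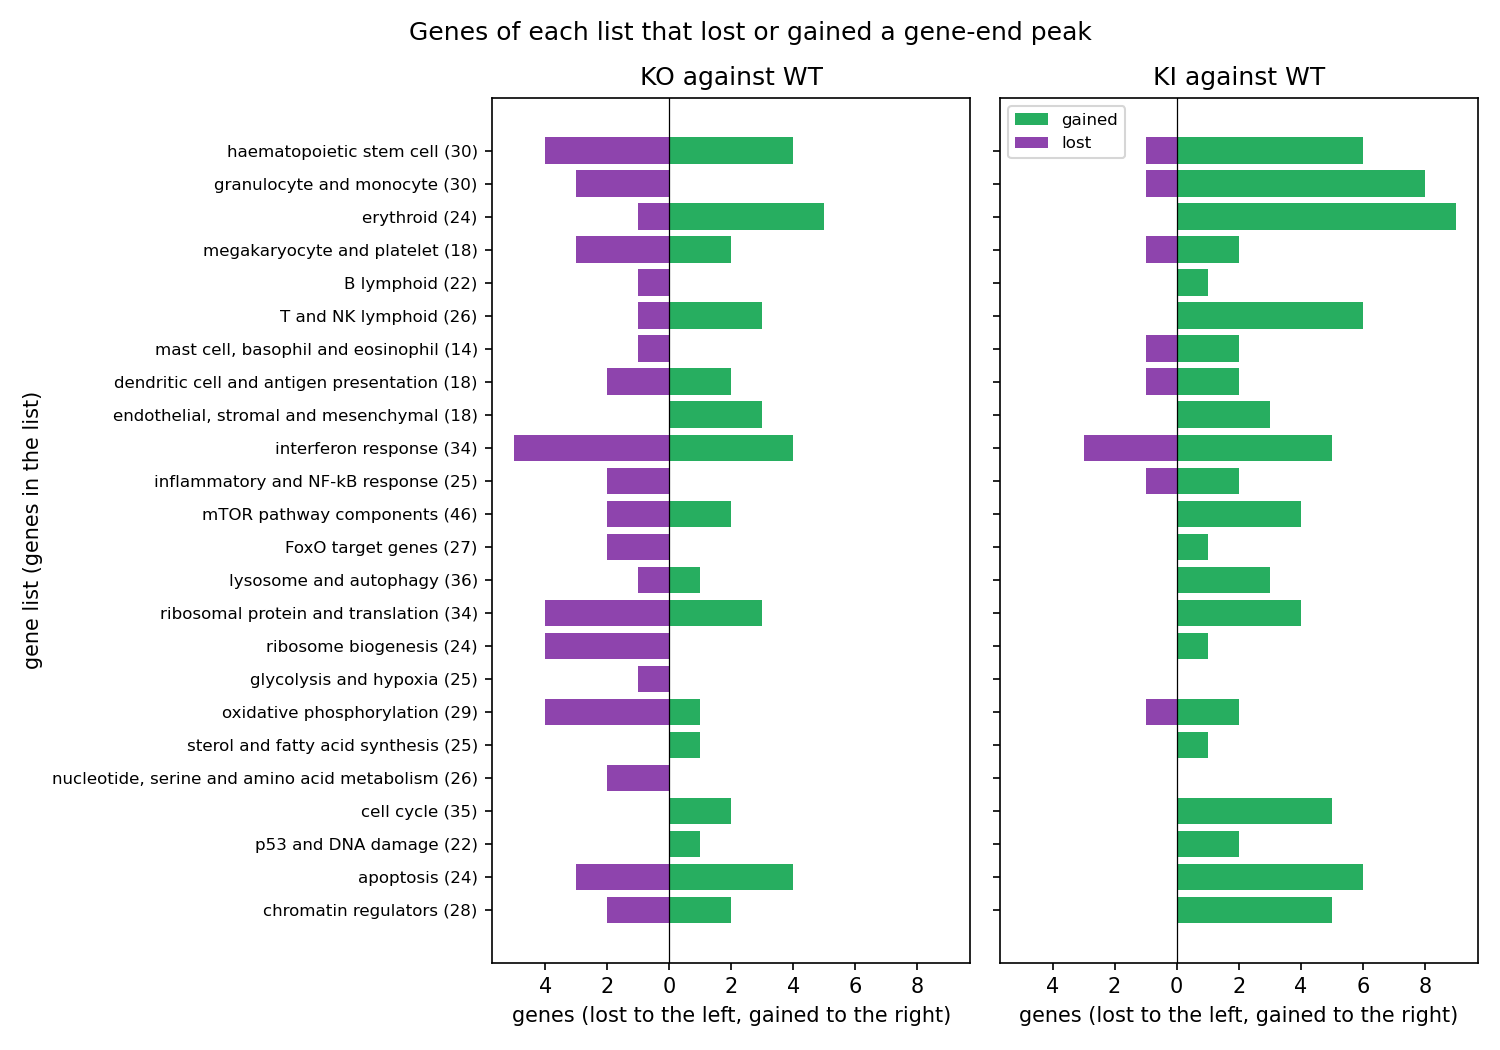
Number of genes of each list (y axis, list size in parentheses) that lost (left) or gained (right) a gene-end peak in KO and in KI against WT (x axis, genes). The erythroid list gained 5 in KO and 9 in KI, and the granulocyte and monocyte list 0 and 8.

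In the growth pathways, the mTOR pathway list (46 genes, 35 in WT) lost 2 in KO and 0 in KI and gained 2 and 4. Mtor was lost in KO and kept in KI, Rptor, the mTORC1 scaffold, was gained in both, and Tsc2, a negative regulator of mTORC1, and Telo2 were gained in KI. The ribosome biogenesis list (24 genes, 22 in WT) lost 4 in KO and 0 in KI, among them Bop1, Pes1 and Taf1a, and gained Nop58 in KI. The WT peak behind the Bop1 loss also overlapped Hsf1. The ribosomal protein and translation list (34 genes, 30 in WT) lost 4 in KO and 0 in KI, with Rps15 and Rpl3 among those lost, and gained 3 and 4, with Rps4x in both and Rpl10a in KI. The 4 gained in KI were all its members without a WT peak and included the 3 gained in KO. These gains stood at percentile 99.9 in KO and 99.98 in KI of random genes without a WT peak, and at 99.2 and 99.5 of draws from the list genes. At equal list size they were 2 and 2. The KO losses of the ribosome biogenesis and ribosomal lists stood at percentiles 95.4 and 78.1 of lists matched on WT score, and no list's KO losses stood above 95.4 there. Among random lists without that matching, KO losses stood at percentile 99.5 for megakaryocyte and platelet, 99.0 for granulocyte and monocyte and 97.9 for interferon response genes.

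The interferon response list (34 genes, 18 in WT) lost 5 in KO and 3 in KI and gained 4 and 5. Mx1, whose promoter drives the Cre transgene, had a gene-end peak in KO and KI and none in WT, and so had the interferon-induced genes Ifit3 and Cxcl10, whereas Gbp2 was lost in KI. In both mutants 4 members were gained and 2 were lost. Those lost in both, named outside the rule, were Ifi47 (67.11 in WT) and Mx2 (52.67 in WT). The inflammatory and NF-kB list lost 2 in KO and 1 in KI, with Cxcl2 in both and Nfkb1 in KO, and gained Il6 and Icam1 in KI.

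Several lists covered metabolism. The oxidative phosphorylation list lost 4 in KO and 1 in KI, with Ndufa9 in both and Mtfp1 in KO, and gained 1 and 2, with Ppargc1b in both. The nucleotide, serine and amino acid list lost Phgdh, which commits carbon to serine synthesis, and G6pdx in KO, and gained none. The glycolysis and hypoxia list lost Slc16a3 in KO. The sterol and fatty acid list gained Elovl6 in both. The lysosome and autophagy list lost Ctsa in KO and gained 1 in KO and 3 in KI, with Map1lc3b in both and Becn1 and Hexa in KI. The FoxO target list lost the pro-apoptotic gene Bcl2l11 and Pdk4 in KO and gained Foxo4 in KI.

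In the lists of cell division and survival, the cell cycle list lost none and gained 2 in KO and 5 in KI, Cdkn1c and Aurkb in both and Ccnb2 and E2f2 in KI. The p53 and DNA damage list lost none and gained 1 in KO and 2 in KI, with Bax in KI. The apoptosis list lost 3 in KO and 0 in KI, Bcl2l11 among them, and gained 4 and 6, with Bmf and Bak1 in both. The chromatin regulator list lost 2 in KO and 0 in KI, among them Bmi1, a Polycomb protein needed for HSC self-renewal, and gained 2 and 5, with Kdm6a and Ezh1 in both and Kdm6b in KI. The Kdm6a peaks (159.08 in KO and 280.08 in KI) were strong but not among the strong peaks absent from WT. They thus overlapped a WT peak that lay outside the 1 kb window, so the Kdm6a gain was not a new peak.

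Peaks in the body or within 10 kb of erythroid genes numbered 15 in WT (0.0866% of the list, 0.0525 to 0.143), 25 in KO (0.130%, 0.0883 to 0.192) and 43 in KI (0.151%, 0.112 to 0.204). For granulocyte and monocyte genes they numbered 20 (0.116%, 0.0748 to 0.178), 12 (0.0625%, 0.0358 to 0.109) and 37 (0.130%, 0.0946 to 0.180). Peaks near haematopoietic stem cell genes numbered 51 (0.295%), 50 (0.261%) and 79 (0.278%). The erythroid share minus that of WT was 0.0437 percentage points in KO (-0.0266 to 0.114) and 0.0648 in KI (-0.00362 to 0.127), and the granulocyte and monocyte share minus that of WT was -0.0530 in KO (-0.121 to 0.00903) and 0.0148 in KI (-0.0575 to 0.0787). These intervals include 0, for erythroid genes in KI and granulocyte and monocyte genes in KO by a narrow margin, and so do those of haematopoietic stem cell genes (-0.0340 in KO, -0.146 to 0.0747, and -0.0163 in KI, -0.124 to 0.0819).

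**Figure D5:**
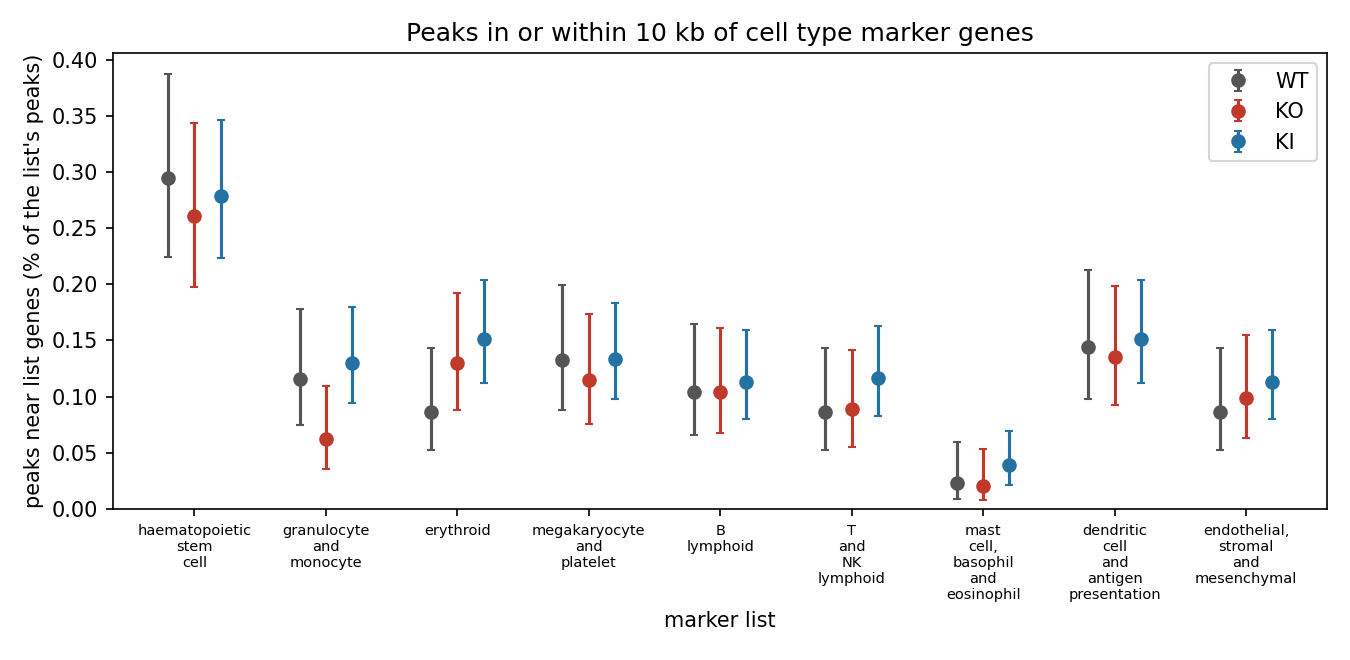
Peaks in or within 10 kb of the genes of each cell type marker list (x axis) as a share of all peaks of the WT, KO and KI lists (y axis, %), with Wilson 95% intervals. KO lies lowest for granulocyte and monocyte genes (0.0625%) and WT lowest for erythroid genes (0.0866%).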

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

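No paired analysis was possible because each genotype had 1 library, and for the same reason no library was left out. The random lists drawn from list genes and those matched on nearby peaks were added after the data were examined, and the other alternatives were planned. Motif content under another window was not run because no genome sequence was used here. Beside having 1 library per genotype, a limit on these results is the unknown read depth, which can change how many weak peaks each list holds.

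Autosomes alone, a tolerance of 1 kb and merging across 500 bp kept every count within 1.5 times and every direction for the overlaps, regions and strong peaks they were run on. The Mtor start peak was present in WT and KI and absent from KO under every gene-end setting. At equal list size, which by construction removes the weakest KO and KI peaks, WT peaks absent from KI rose to 4255, and KI peaks absent from WT and KO fell to 4373 and 4408. The excess of WT peaks absent from KO over those absent from KI went from 12.5 to 4.16 percentage points. The Jaccard index of WT with KI minus that of WT with KO turned from -0.0167 to 0.0323. Regions with a WT peak alone numbered 3126 and those with KO and KI alone 1745. List genes lost and gained in KI numbered 33 and 40, and gene-end shares were 48.4% in KO and 50.6% in KI.

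A reciprocal overlap of 50% left 3716 WT and 5134 KO peaks absent from KI and an excess of 11.2 points. Peaks of 200 bp left 4038, 5069 and 10.7 points. In the stronger 50% of each list, which holds fewer peaks, 1690 WT and 2612 KO peaks were absent from each other, 562 WT and 907 KO peaks from KI, 6073 KI peaks from WT and 5495 from KO, and the Jaccard difference was -0.0352. Among the top 10% of each list, 1 WT peak was absent from KO and 2 from KI, 2 KO peaks were absent from WT and 0 from KI, and 5 KI peaks were absent from WT and 1 from KO. Among the top 50% these counts were 446 and 104, 850 and 190, and 2422 and 2095. Gene-end shares in WT, KO and KI were 47.8%, 43.2% and 35.0% within 500 bp and 55.6%, 51.2% and 43.4% within 2500 bp, in the same order. Of the 96 counts of single lists, 34 of those at equal list size, 14 within 500 bp and 22 within 2500 bp moved by over 1.5 times. Random lists without matching on WT score moved 5 of 48 percentiles of losses above the upper tail limit: in KO granulocyte and monocyte (99.0), megakaryocyte and platelet (99.5) and interferon response (97.9), and in KI interferon response (98.8) and mast cell, basophil and eosinophil (98.3). Draws from the list genes moved 14 of 48 percentiles of gains across a tail limit, and draws matched on nearby WT peaks and gene length moved 3 of 48, those of haematopoietic stem cell genes in both mutants and of lysosome and autophagy genes in KI.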

Other observations

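List-specific peaks in or near marker genes were set among random lists matched on nearby WT peaks and gene length. This measure, and the tests below on the length of the KI list, on the strong KI peaks that 1 other list lacked, on chance loss of the Mtor start peak and on stretches of DNA, were chosen after the results were seen. The split of merged regions at equal list size and the test of DNA around Mtor were set before. Percentiles rest on counts of each peak once per gene. Near granulocyte and monocyte genes, 9 WT peaks (10 counted per gene) were absent from KO (percentile 99.7 of 2000 random lists) and 1 KO peak was absent from WT (percentile 1.93), while 18 KI peaks (20 counted per gene) were absent from WT (percentile 98.8). Near erythroid genes, 12 KO peaks (percentile 99.1) and 27 KI peaks (percentile 99.95) were absent from WT, and 2 WT peaks were absent from KO. Near haematopoietic stem cell genes, 17 WT peaks were absent from KO (percentile 96.0), 12 from KI (percentile 99.5), and 40 KI peaks (41 counted per gene) were absent from WT (percentile 99.6). Of the 96 percentiles of this kind over all 24 lists, 14 lay outside the middle 95% of their draws, where chance gives about 5%. The others were dendritic cell genes (97.8) and inflammatory genes (98.4) for KO peaks absent from WT, inflammatory genes (98.3) for KI peaks absent from WT, glycolysis (2.25) and cell cycle genes (1.93) for WT peaks absent from KO, and p53 (2.48) and chromatin regulator genes (0.375) for WT peaks absent from KI. List genes as a whole gained gene-end peaks at about 2 times the mean of random genes (39 against 20.5 in KO and 78 against 38.8 in KI), so a baseline of random genes can overstate gains near these lists. The percentiles describe 3 libraries and carry no replicate error, and both mutants were compared with the same WT list. Their draws were not matched on WT score. Of WT peaks, 57.4% were absent from KO in the lowest score class and 0.393% in the highest. High percentiles for WT peaks absent from a mutant may therefore reflect weak peaks. For gene-end losses, matching on WT score moved granulocyte and monocyte genes in KO from percentile 99.0 to 95.4. Haematopoietic stem cell genes in KI moved from 77.7 to 67.7 and erythroid genes in KO from 69.1 to 94.8.

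In a zinc finger gene cluster on chromosome 13, the WT list had a peak at the end of Zfp429 (67399332 to 67400035) that both mutants lacked, and KO and KI had a peak at the end of Zfp58 (start 67500077 in KO) that WT lacked. On chromosome 7, KI had strong peaks missing from WT at both Trim5 and Trim12a, and KO had a strong peak at Trim12a and a weaker one at Trim5.

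The Mtor start peak was the highest-scoring WT peak that KO lacked. Chance loss at the calling threshold would need such peaks to be lost often enough to reach 1 gene named in advance. Of the other 1730 WT peaks in the top 10%, 0 were absent from KO (upper limit 0.222%), and their KO peaks had a median score of 269.6 against a lowest value of 50 in the list, with 7 of them under 80 and the lowest at 57.77. These values argue against chance loss. Deletion of the floxed segment by Cre is the explanation the design names. It was not tested, since neither the deleted segment nor reads were used here, and a peak can be missing because its DNA is.

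Strong peaks shared by KO and KI and missing from WT could be read as a common effect of changing Mtor. A simpler account is that peaks were missed at random in 1 list, which predicts that WT lacks as many as KO. The merged regions at equal list size met this, with WT lacking 49.8% (48.1 to 51.4) of the 3506 regions that exactly WT or exactly KO lacked. Equal lengths tie each list's sum with its regions alone (4887 in WT and 4892 in KO), which leaves this split free to move. The cut itself also made absences: regions with a WT peak alone numbered 1808 in the full lists and 3126 at equal size. Of 215 strong KI peaks that exactly 1 other list lacked, WT lacked 117 (54.4%, 47.7 to 60.9) and KO 98. In the full lists, where the KO list is longer, WT lacked 58.1% (56.8 to 59.3) of such merged regions, above an even split. That split was added later. Equal numbers of real changes would also give an even split, so the split at equal size does not show that peaks were missed at random. Stretches of DNA that differ between the WT and the mutant mice, such as strain haplotypes, stay open: 14 of the 117 peaks lay within 500 kb of another, against 9.59 on average in random draws (percentile 84.8), and 14 of the 98 that KO lacked did so (percentile 97.0). An effect of genotype on part of these peaks remains untested. KO and KI mice carried Cre and WT mice did not, so an effect of Cre itself cannot be told apart from one of the Mtor alleles.

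The length of the KI list may come from detection depth, from batch or from genotype. The share of KI peaks absent from WT fell from 83.1% in the lowest 25% of scores to 2.0% in the top 25%, but every pair of lists showed such a fall, so it does not separate depth from the rest. If batch alone set KI apart, WT and KO would be the closest pair. At equal list size they were the least similar pair, with a Jaccard index of 0.501 against 0.533 for WT and KI and 0.521 for KO and KI, while in the full lists they were the most similar, at 0.499 against 0.482 and 0.474, so the ranking turns with list length and decides nothing. Batch and the KI genotype cannot be told apart because the labels confound them.

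Further hypotheses were tested on named genes, with predictions written before their results were seen. Erythroid gains may be no more than the rate of all list genes: the lower of the KO and KI percentiles was 91.8 and the higher 95.4, both inside the middle 95% of draws. Those draws held the erythroid genes themselves and both values were high, so they do not show equal rates. Among genes matched on nearby WT peaks and gene length the percentiles were 99.0 in KO and 99.97 in KI. Granulocyte and monocyte gains in KI may follow the longer KI list. They fell from 8 in the full list to 1 at equal list size, so most of them depended on weak KI peaks. The 1 left, Mmp8, against 0 in KO is too few to decide whether any gain remains. Mmp8 had 1 peak in the gene body or within 10 kb in each of the WT, KO and KI lists. The Mx1 peak of both mutants could come from promoter copies in the Cre transgene. Of the 15 other interferon genes without a WT gene-end peak, 20% (7.05 to 45.2) were also gained in both, against 12.8% (9.13 to 17.7) of 234 other list genes, which leaves this open. The test counted gains alone, and 2 interferon genes were lost in both mutants. Flanking DNA brought in with the knock-in allele predicted more WT peaks absent from KI near Mtor. Within 10 Mb the share was 12.3% (8.57 to 17.3, 27 of 220), against 13.1% elsewhere. Overlap of the intervals had been set as the outcome against this explanation, but the interval allows an excess of several points. KI mice also carried a floxed allele, whose chromosome could still give a peak where the knock-in one does not. The share absent therefore cannot decide, and the explanation stays open.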
